A study of Homo sapiens with 15 samples.

How the data were processed

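RNA of EcR-RKO/KLF4 cells, a derivative of the RKO colon cancer line in which an ecdysone-type receptor lets a steroid inducer switch on the transcription factor KLF4, was measured on 15 Affymetrix HU133A arrays, as the labels name them. The cells received ponasterone A, the inducer, or vehicle for 1, 2, 4, 6, 8, 12 or 24 h, with 1 array per arm and time, and 1 further array was made at 0 h. The series text speaks of vehicle for the controls, whereas the sample labels call them untreated. The series text names Trizol for the extraction and the sample labels name RNeasy, and which was used for which array was not given in the sources used here. Biotin-labelled cRNA was hybridised, per the labels.

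The deposited table holds 1 intensity per probe set and array, on a linear scale, which the authors made with MAS5 per the submitters' processing notes. The version of MAS5 and any filter on the table were not given in the sources used here. The mean of each column, taken between its percentiles 2 and 98, was 150 in all 15 columns, so the columns were used as deposited. The table had 22283 probe sets, of which 68 control probe sets were left out of the tests. Values below the percentile 25 of the whole table, an intensity of 22.3, were raised to it, and log2 was taken. A difference against values at this floor understates the true one. The 12885 probe sets at or above their array's median in at least 3 arrays were tested, whatever the arm.

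Gene names came from the platform annotation. It gave 1 symbol to 19071 probe sets, several to 1043 and none to 2169, and 19059 of those with 1 symbol were matched by Entrez identifier to the gene table of assembly GRCh38.p14, which was used for names only. Of the tested probe sets 11395 had 1 symbol. A gene was represented by its probe set with the highest mean log2 value, which gave 7983 genes.

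Tests were fitted with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The average effect of induction was induced minus control over all 7 time pairs with time as a block, which leaves 6 residual degrees of freedom. The early effect (1, 2 and 4 h), the late effect (6, 8, 12 and 24 h) and their difference came from 1 fit with time as a block and 5 residual degrees of freedom. The time trend in controls was the slope on log2(hours + 1) over the 7 control arrays and the start array, with 6 residual degrees of freedom. Each arm had 1 array per time, so the residual is the disagreement of the differences between time points. The p-values measure that spread, and nothing in the labels says that the arrays came from separate cultures. At single times there is no test. For KLF4 the mean of the 7 paired differences was set against the exact sign-flip permutation test over all flips. The number of arrays limits the precision, and no sequencing depth applies.

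Sets of functionally related genes, 38 in all, were fixed from textbook knowledge, and 37 of them had at least 5 measured members. The themes of cholesterol biosynthesis, translation, transcription, DNA replication, DNA repair, cell cycle and epithelial differentiation were chosen with knowledge of published work on KLF4 in this line and are not independent of it, although the members were not taken from it. Markers of fibroblasts, leukocytes and endothelial cells were included because a pure culture should lack those cells. Lists were tested with camera at a preset correlation of 0.01 on the representative probe sets, with Benjamini-Hochberg adjustment over the 37 lists, and again with an estimated correlation.

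Genes were named by a rule. For the average and the late effect it took the 12 largest rises and the 12 largest falls among probe sets past the threshold with the same sign in every pair of the window, for the other comparisons the 6 largest of each, and where fewer than 5 passed, the largest ones as not having passed. KLF4 and RXRA were always named, and each called list gave up to 4 members. The samples, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, other floors and filters, other variance settings, array weights, no time block, other windows and slopes, other list tests, and leaving out each time pair or array in turn. Comparisons within 1 arm, and the list test of the late minus early effect with its alternatives, were added later.

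The fits were tested on simulated data for 12885 probe sets. Of 67 probe sets changed by a log2 value of 1, the average effect recovered 76.1%, the early effect 56.7%, the late effect 58.2%, the late minus early effect 32.8% and the time trend in controls 7.46%. At a log2 change of 2 the shares of 66 were 98.5%, 92.4%, 87.9%, 74.2% and 63.6%, and at 0.5 they were 23.9%, 7.46%, 13.4%, 0% and 0%. Unchanged probe sets made up 5.04%, 2.8%, 4.5%, 7.79% and 7.84% of the calls. For the lists of the average effect, simulated over 7983 genes, 2 of 2 shifted lists and 0 others were called. The simulated noise was independent between genes, with no grouping of the arrays. The list result therefore cannot show how camera at the preset correlation behaves when genes are correlated. Far fewer probe sets were changed than the average effect called in the data. The simulation was written after a first run on the deposited values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.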

Results

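The response of a colon cancer line to induced KLF4, a zinc finger transcription factor of the Krüppel-like family, was followed over 24 h. The series holds 7 arrays of cells given ponasterone A, 7 arrays of control cells and 1 start array at 0 h. The values are MAS5 intensities as deposited. Median intensity was 73.5 to 86.4 in the induced arrays, 64.8 to 73.9 in the control arrays and 76.9 in the start array. The comparisons ask which transcripts differed between the arms on average, which differed early or late, and which moved in the control cells alone.

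The arrays fell into groups before any gene was considered. Across the tested probe sets, which are not independent replicates, the median correlation was 0.937 between control arrays, 0.932 between induced arrays and 0.894 between the arms. The start array, which had received no inducer, had a median correlation of 0.941 with the induced arrays and 0.905 with the controls. The first principal component held 34.6% of the variance and separated the control arrays from the induced and start arrays. Among the control probe sets outside the tests, those for 18S ribosomal RNA had a geometric mean intensity of 9.73 over the induced arrays, 10.4 in the start array and 270 over the control arrays. The induced and start values lie below the floor of 22.3. Those for 28S ribosomal RNA were at 40.4, 34.4 and 147. The hybridization spike-ins, added in fixed amounts, were at 172 in the induced, 226 in the start and 374 in the control arrays. Single arrays reached at most 208 in the induced and at least 238 in the control arm, so the spike-ins do not place the start array with either arm. The Alu control probe set was 2.59-fold higher in the control than in the induced arrays. The 3' to 5' ratio, a sign of RNA quality, was 0.737 to 0.847 in the induced, 0.837 in the start and 0.828 to 1.12 in the control arrays for GAPDH, and 0.763 to 0.882, 0.848 and 0.804 to 0.967 for ACTB. For differences that are constant over time, the arm and this grouping of the arrays cannot be told apart, so the distance of the start array from the mean of the controls is given with the called gene groups, at least where a group is first described. It is the same in every comparison. That distance and the effect of induction use the same control arrays.

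**Figure D1:**
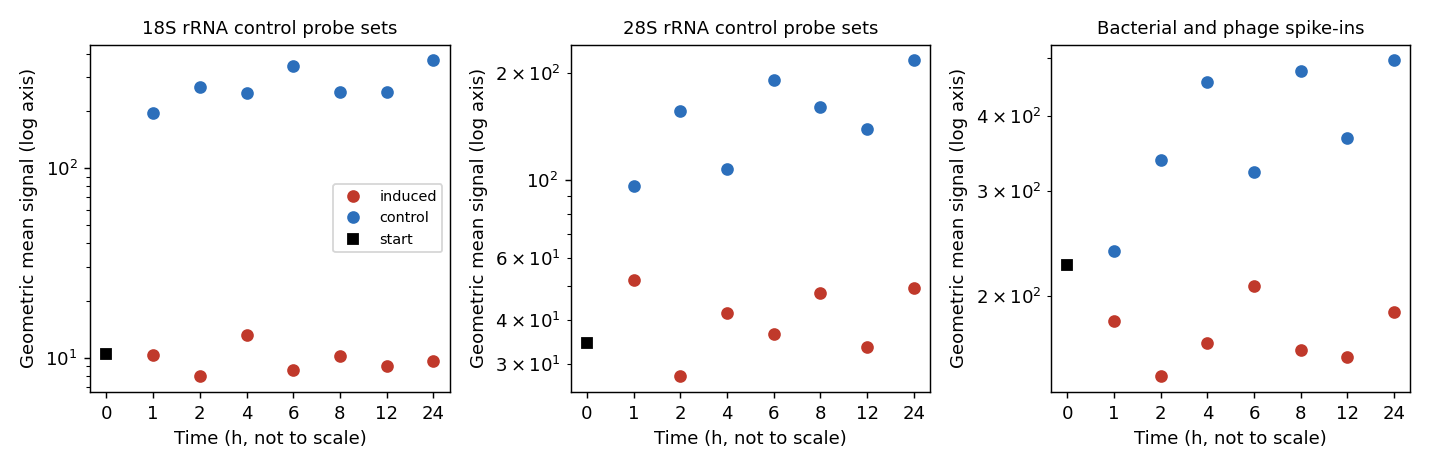
Intensity on a log axis of the 18S, 28S and spike-in control probe sets in each array, by time in hours and arm. The 18S value lies between 7.96 and 13.2 in the induced arrays, at 10.4 in the start array and between 196 and 369 in the control arrays.

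KLF4 itself was read by a pair of probe sets for the endogenous gene, which need not see a transgene. On the more responsive of them, the intensity in the induced arrays was 29 at 1 h, 97.3 at 2 h, 108.8 at 4 h, 244.7 at 6 h, 433.7 at 8 h, 426.5 at 12 h and 432.5 at 24 h. The 7 control arrays averaged 55.1 ± 30.2 (SD, n = 7), and the start array gave 85.8. The log2 difference between the arms was 0.08 at 1 h, -0.02 at 2 h, 1.75 at 4 h, 1.49 at 6 h, 3.10 at 8 h, 2.65 at 12 h and at least 4.28 at 24 h, a ratio of at least 19.4, since the control intensity at 24 h, 21.9, lay below the floor of 22.3 and was raised to it. The mean difference was 1.91 ± 0.59 (SE, n = 7 pairs), higher in 6 of 7 pairs, with p = 0.0312 in the two-sided exact sign-flip test, whose smallest p is 0.0156. After quantile normalization the mean was 1.74 with an exact p of 0.0625. Leaving out the 1, 4, 6, 8, 12 or 24 h pair also gave an exact p of 0.0625, with means of 2.21, 1.93, 1.97, 1.71, 1.78 and 1.51. With 6 pairs the smallest exact p is 0.0312, which was reached without the 2 h pair at a mean of 2.23. While the negative 2 h difference was kept, 0.0625 was the lowest p possible, so it is not by itself a sign of a weaker difference. On the other probe set the mean difference was 0.49 ± 0.18 (SE, n = 7 pairs), with an exact sign-flip p of 0.0469 and a limma adjusted p of 0.0623. RXRA, a partner of the ecdysone receptor, was lower on average on 1 of its probe sets, at -0.28 ± 0.08 (limma adjusted p = 0.0137), and stood at -0.19 ± 0.12 (adjusted p = 0.23) on another.

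**Figure D2:**
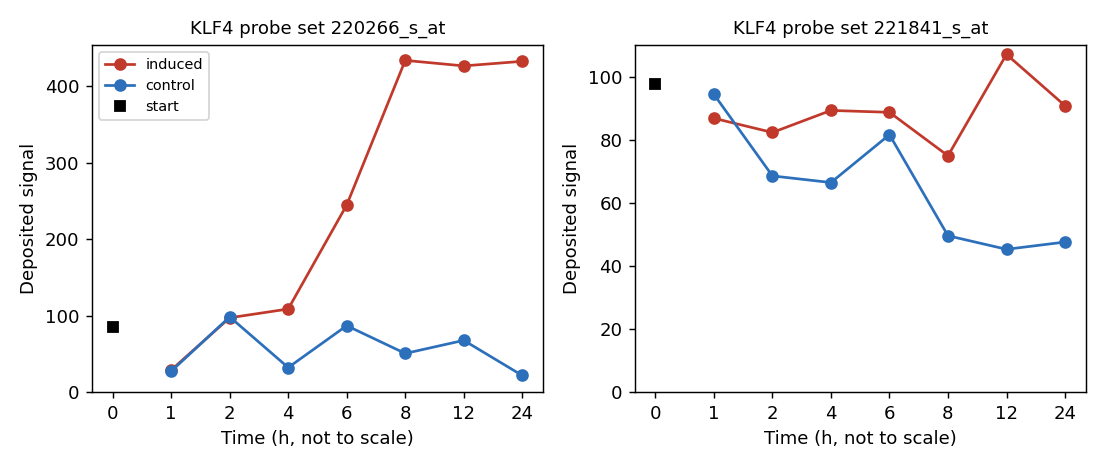
KLF4 intensity on both probe sets against time in hours for the induced, control and start arrays, 1 array per point. On the more responsive set the induced arrays lie at 426.5 to 433.7 from 8 h on, and the control arrays at the same times lie between 21.9 and 67.8.

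On average over 1 to 24 h, genes of sterol synthesis and the respiratory chain were lower in the induced arrays, in list calls that were lost with an estimated correlation (adjusted p = 0.387 and adjusted p = 0.275). PCLO, a scaffold protein of the presynaptic active zone, was at -3.04 ± 0.10 on the log2 scale (adjusted p = 3.12e-09), S100A10, the annexin A2 partner, at -2.77 ± 0.24, URI1 at -2.58 on 1 probe set, while its other probe set went the opposite way, and MLLT11 at -2.49 ± 0.11. ERCC2, a helicase of the general transcription factor TFIIH, was at -2.27, RBMS2 at -2.26, NAV3 at -2.16, the origin recognition subunit ORC3 at -1.96 and the muscle ankyrin repeat protein ANKRD1 at -1.95. LAS1L was at -1.82, NDRG4 at -1.81 and MPPE1 at -1.70. RRP15, a factor of ribosomal RNA processing, was at 2.48 ± 0.17 (adjusted p = 2.9e-06). SCD5, a stearoyl-CoA desaturase, was at 1.97 ± 0.14 and RECK, a membrane-anchored inhibitor of matrix metalloproteinases, at 1.77 ± 0.11. CPA3 and SLC13A3 were at 2.00, KSR1 at 1.88, APOL6 at 1.84, POPDC3 at 1.79, TM4SF1 at 1.75, DLEC1 at 1.58 and DEPTOR at 1.54. PLEKHG3 was at 2.00 on 1 probe set, with its other probe set opposite. All of these went 1 way in 7 of 7 pairs. ERCC2 was at the floor in 6 of the 7 induced arrays, S100A10 in 4, NDRG4 in 2 and MPPE1 and ORC3 in 1. KSR1 was at the floor in 6 of the 7 control arrays, PLEKHG3, POPDC3 and TM4SF1 in 5, SLC13A3 in 4, CPA3 in 3, DEPTOR and DLEC1 in 2 and APOL6 in 1. The size of these differences, and so their order, depends on the floor. The start array lay -3.13 from the control mean for PCLO, -2.33 for MLLT11, 2.30 for RRP15, 1.88 for SCD5 and 1.70 for RECK, and -0.57 for NAV3 and -0.85 for both LAS1L and ORC3. By intensity, ANKRD1 was at 44 in the start, 62.5 to 135.6 in the induced and 247.4 to 427.1 in the control arrays. In that order APOL6 was at 143, 82.1 to 187.4 and 12.9 to 60.2. CPA3 was at 103.9, 81.1 to 164.8 and 11.6 to 98.4, and DLEC1 at 114.8, 74.5 to 135.9 and 15.7 to 56.7. For these genes the start array, without inducer, lay on the side of the induced arrays. The distance is not given for the other genes named here.

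In all, limma called 4292 of the 12885 probe sets for the average effect, 2345 higher and 1947 lower in the induced arrays, and 534 of them differed at least 2-fold. They stood for 1830 genes higher and 1443 genes lower.

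Camera called 12 of 37 lists for the average effect, 11 lower and 1 higher, and 0 with an estimated correlation. Of 17 measured genes of cholesterol biosynthesis, 0 were higher, 10 were lower and 7 did not pass, with 10 lower when adjusted over the list alone. NSDHL was at -1.29 ± 0.18, HMGCS1 at -1.23 ± 0.20 and FDPS, the farnesyl diphosphate synthase, at -1.10 ± 0.15. The list's median was -0.61 (adjusted p = 2.18e-05, and adjusted p = 0.387 with an estimated correlation), and the start array lay -0.72 from the controls. Of 54 genes of oxidative phosphorylation, 2 were higher, 28 lower and 24 did not pass, with 2 higher and 30 lower adjusted over the list alone. COX6A1 was at -1.04 ± 0.13 and NDUFV2 at -0.90 ± 0.09. The median was -0.31 (adjusted p = 1.05e-09, and adjusted p = 0.275 with an estimated correlation), against -0.28 in the start array. Of 43 DNA replication genes, 3 were higher, 11 lower and 29 did not pass, with 3 and 12 adjusted over the list alone. LIG1, the replicative DNA ligase, was at -1.13 ± 0.14 and the polymerase subunit POLD1 at -1.03 ± 0.12. The median was -0.17 (adjusted p = 0.0076, and adjusted p = 0.387 with an estimated correlation), against -0.10 in the start array. These lists were also called after quantile normalization.

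For 52 cytosolic ribosomal proteins, 46 were lower and 6 did not pass, with 47 lower adjusted over the list alone, and the median of -0.47 (adjusted p = 5.04e-22) turned to 0.039 after quantile normalization (adjusted p = 0.335). With an estimated correlation the adjusted p was 0.353, and the start array lay -0.55 from the controls. RPL41 was at -0.91 ± 0.12 and RPS24 at -0.71 ± 0.08. For 30 translation factors, 7 were lower and 23 did not pass, with 6 lower adjusted over the list alone, and the median of -0.083 (adjusted p = 0.0303) turned to 0.11 after quantile normalization. Camera gave an adjusted p of 0.422 with an estimated correlation and 0.0893 without the 24 h pair, and the start array lay -0.064 from the controls. EIF3G was at -0.43 ± 0.10, and EIF4G1 at -0.50 ± 0.09 on 1 probe set, with its other probe set opposite.

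Of 32 proteasome genes, 4 were higher, 20 lower and 8 did not pass, with 4 and 22 adjusted over the list alone and PSMD8 at -1.08 ± 0.16. Their median of -0.34 had an adjusted p of 6.93e-05, which became 0.403 with an estimated correlation and 0.0683 after quantile normalization. The start array lay -0.036 from the controls. Of 49 spliceosome genes, 5 were higher, 14 lower and 30 did not pass, with 7 and 17 adjusted over the list alone and SNRPD2 at -1.04 ± 0.08. Their adjusted p of 0.0076 became 0.353 with an estimated correlation and 0.356 after quantile normalization, and the start array lay -0.053 from the controls. Of 15 genes of intestinal differentiation, 5 were higher and 10 did not pass, with 5 higher adjusted over the list alone. GPA33, a glycoprotein of intestinal epithelium, was at 1.11 ± 0.20 and the carbonic anhydrase CA1 at 0.94 ± 0.19. The median of 0.47 (adjusted p = 0.0257) had an adjusted p of 0.353 with an estimated correlation. After quantile normalization the median was 0.344 and the adjusted p 0.122. The start array lay 0.21 from the controls.

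The other called lists lay near the threshold. Of 35 genes of RNA polymerase II and its general factors, 3 were higher, 6 lower and 26 did not pass, the same 3 and 6 adjusted over the list alone, with POLR2L at -0.74 ± 0.15. The adjusted p of 0.0324 was 0.387 with an estimated correlation, 0.122 after quantile normalization, 0.0516 without the 1 h pair and 0.0548 without the 4 h pair. The start array lay -0.058 from the controls. Of 21 genes of the list G1/S cyclins and E2F targets, 1 was higher, 5 lower and 15 did not pass, and 1 and 5 adjusted over the list alone. RRM2, a ribonucleotide reductase subunit, was at -1.06 ± 0.09 and TYMS, thymidylate synthase, at -0.92 ± 0.09. The list's adjusted p of 0.0451 was 0.387 with an estimated correlation, 0.155 after quantile normalization, and 0.0601, 0.0766 and 0.0524 without the 2, 6 and 24 h pairs. The start array lay 0.0042 from the controls. Of 19 heat shock proteins, 7 were lower and 12 did not pass, with 2 higher and 7 lower adjusted over the list alone and SERPINH1, a collagen chaperone, at -1.66 ± 0.22. The adjusted p of 0.0474 was 0.445 with an estimated correlation, 0.517 after quantile normalization, and 0.0678, 0.0601, 0.0759 and 0.058 without the 1, 2, 12 and 24 h pairs. Here the start array lay 0.19 from the controls, opposite in sign to the effect. Of 12 housekeeping genes, 1 was higher, 6 lower and 5 did not pass, the same 1 and 6 adjusted over the list alone, with GUSB at -0.36 ± 0.09. Their adjusted p of 0.0201 was 0.353 with an estimated correlation and 0.968 after quantile normalization, and the start array lay -0.17 from the controls.

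Lists not called for the average effect included G2/M and mitosis (46 genes, adjusted p = 0.0616), epithelial junctions (10 genes, median 0.54, adjusted p = 0.0656), cornified envelope and barrier (15 genes, adjusted p = 0.2), keratins (6 genes, adjusted p = 0.594), DNA repair (34 genes, adjusted p = 0.691) and ribosome biogenesis (31 genes, adjusted p = 0.809). Among markers of other cell types, 3 of 9 leukocyte markers were higher and 6 did not pass (list adjusted p = 0.0625), and 1 of 5 fibroblast markers was higher and 4 did not pass (adjusted p = 0.193). The start array lay 0.52 from the controls for leukocyte markers and 0.37 for fibroblast markers. Fewer than 5 endothelial markers were measured, so that list was not tested.

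In the first 4 h, the induced arrays had higher GDF15, a stress-induced cytokine, and lower sterol and proteasome genes, in list calls that were lost with an estimated correlation (adjusted p = 0.213 for each). GDF15 was at 2.29 ± 0.26 (adjusted p = 0.000165), and its intensity was 2491 at 1 h and 2480 at 2 h in the induced arrays against 394 in the start array. RRP15 was at 2.87, CPA3 at 2.52, HOXC5 and SLC13A3 at 2.35 and SDHAF3 at 2.18. PCLO was at -2.99, the spindle protein TACC3 at -2.89, MLLT11 at -2.79, LAS1L at -2.72 and URI1 at -2.75. TACC3 lost its call without the filter on low values. FGFR3, a fibroblast growth factor receptor, was at -2.74 ± 0.25 on 1 probe set, with its other probe set opposite, and URI1 also had a probe set opposite. Over the whole course HOXC5 and SDHAF3 were at the floor in 1 control array each, and FGFR3 and TACC3 in 1 induced array each. Limma called 3090 probe sets, 1572 higher and 1518 lower, for 1259 genes higher and 1105 lower. Without the 2 h pair the count was 1810 and without the 4 h pair 1645. KLF4 on its more responsive probe set was at 0.61 ± 0.44 (adjusted p = 0.337).

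Of the 17 cholesterol genes, 13 were lower early and 4 did not pass, with 1 higher and 14 lower adjusted over the list alone. IDI1 was at -1.94 ± 0.17, NSDHL at -1.85 ± 0.19 and HMGCS1 at -1.80 ± 0.22. Their median was -0.97 (adjusted p = 2.66e-09, and adjusted p = 0.213 with an estimated correlation). Of 32 proteasome genes, 1 was higher, 20 lower and 11 did not pass, the same 1 and 20 adjusted over the list alone, with PSMD8 at -1.54 ± 0.17 and PSMB6 at -1.22 ± 0.17. Their median was -0.52 (adjusted p = 3.28e-08, and adjusted p = 0.213 with an estimated correlation). Of 24 genes of the amino acid response, targets of ATF4, 8 were higher and 16 did not pass, with 9 higher adjusted over the list alone. CTH, which makes cysteine from cystathionine, was at 1.99 ± 0.37, and PCK2 and the transcription factor CEBPG were both at 0.99. The median was 0.35 (adjusted p = 0.0192, and adjusted p = 0.486 with an estimated correlation), and without the 1 h pair it was 0.20 with an adjusted p of 0.443. Here the start array lay -0.41 from the controls. Of 24 p53 targets, 5 were higher, 1 was lower and 18 did not pass, with 6 and 1 adjusted over the list alone. The death receptor TNFRSF10B was at 1.20 ± 0.18 and RPS27L at 0.80 ± 0.15. The median was 0.38 (adjusted p = 0.0214, and adjusted p = 0.289 with an estimated correlation), and the start array lay 0.030 from the controls.

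Of 54 oxidative phosphorylation genes, 2 were higher early, 23 lower and 29 did not pass, with 2 and 26 adjusted over the list alone. Their list test gave an adjusted p of 5.02e-08, and 0.213 with an estimated correlation. Of 43 DNA replication genes, 1 was higher, 9 lower and 33 did not pass, with 2 and 11 adjusted over the list alone and the helicase subunit MCM5 at -1.33 ± 0.21. For the list the adjusted p was 0.00985, and 0.39 with an estimated correlation. Of 46 genes of G2/M and mitosis, 1 was higher, 9 lower and 36 did not pass, the same adjusted over the list alone, with FOXM1 at -1.24 ± 0.16 and CDK1 at -0.70 ± 0.13. By camera the adjusted p was 0.00906, which became 0.632 with an estimated correlation and 0.0956 without the 4 h pair, and the start array lay -0.074 from the controls. Of 8 core histone genes, 5 were lower and 3 did not pass, the same adjusted over the list alone, with H2BC9, at the floor in 2 induced arrays, at -2.22 ± 0.39. As a list they had an adjusted p of 0.0309, which became 0.428 with an estimated correlation and 0.114 without the 1 h pair, and the start array lay -0.25 from the controls. These lists and those of the preceding paragraph were also called after quantile normalization.

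The ribosomal protein list, with 1 higher, 39 lower and 12 not passed and with 1 and 41 adjusted over the list alone, had an early median of -0.56 (adjusted p = 6.27e-18) that turned to 0.096 and a call in the opposite direction after quantile normalization (adjusted p = 0.0377). With an estimated correlation its adjusted p was 0.289. The remaining early calls ended after quantile normalization. Of 19 heat shock proteins, 1 was higher, 9 lower and 9 did not pass, with 3 and 9 adjusted over the list alone. SERPINH1 was at -2.48 ± 0.15 and HSPB1 at -1.55 ± 0.17. Their list had an adjusted p of 0.00977, against 0.428 with an estimated correlation and 0.108 after quantile normalization. Of 32 genes of hypoxia and glycolysis, 3 were higher, 9 lower and 20 did not pass, the same adjusted over the list alone. ALDOA was at -1.18 ± 0.13 and the glucose transporter SLC2A3 at -1.43 ± 0.17. Camera gave an adjusted p of 0.0282, against 0.289 with an estimated correlation, 0.274 after quantile normalization and 0.0766 without the 4 h pair, and the start array lay -0.14 from the controls. Of 15 intestinal differentiation genes, 5 were higher and 10 did not pass, with 7 higher adjusted over the list alone and SPINK4, at the floor in 3 control arrays and 1 induced array, at 2.07 ± 0.39. Their list test gave an adjusted p of 0.0298, against 0.312 with an estimated correlation, 0.108 after quantile normalization and 0.0915 without the 4 h pair. RNA polymerase II genes (2 higher, 8 lower, 25 not passed, with 3 and 9 adjusted over the list alone) had a median of -0.243 and an adjusted p of 0.0192, against 0.289 with an estimated correlation. After quantile normalization their median was -0.245 and the adjusted p 0.0517. Spliceosome genes (5 higher, 14 lower, 30 not passed, with 7 and 18 adjusted over the list alone) had 0.00457, against 0.289 and 0.158. Housekeeping genes (4 lower, 8 not passed, the same adjusted over the list alone) had 0.00316, against 0.213 and 0.385. Of the list members named for the early effect, 59 in all, 40 kept their call without the filter on low values. With early as 1 and 2 h 36 kept it, and CEBPG and SPINK4 were among those that lost it.

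From 6 to 24 h, KLF4 and metallothioneins, small metal-binding proteins, were higher in the induced arrays. The metallothionein list call was lost with an estimated correlation (adjusted p = 0.415), and the start array, without inducer, lay 1.01 from the controls against a late median of 0.95. KLF4 on its more responsive probe set was at 2.88 ± 0.38 (adjusted p = 0.00121), higher in all 4 late pairs. RRP15 was at 2.18, TM4SF1 at 1.92, SCD5 at 1.89 and LPAR1, a receptor for lysophosphatidic acid, at 1.80 ± 0.24 (adjusted p = 0.00121). PLEKHG3 was at 1.87 on 1 probe set, with its other probe set opposite, DLEC1 and KSR1 at 1.77 and ZNF287 at 1.76. GDF11 was at 1.79, GUCY1A1 at 1.77 and POPDC3 at 1.76. S100A10 was at -3.09, PCLO at -3.08, URI1 at -2.45, NAV3 at -2.32, ANKRD1 and RBMS2 at -2.30, MLLT11 at -2.27, ERCC2 at -2.22, ORC3 at -1.92, SLC12A8 at -1.80, SLC2A3 at -1.71 and NDRG4 at -1.65. Besides the genes already given, GUCY1A1 was at the floor in 4 control arrays, GDF11 in 2 and ZNF287 and KLF4 in 1, and SLC12A8 in 1 induced array. Of these 24 genes GDF11 lost its call without the 6, 12 or 24 h pair, and GUCY1A1, POPDC3 and SLC12A8 lost theirs without the 24 h pair. Without the filter on low values KLF4 (adjusted p = 0.0533), GDF11, GUCY1A1, ZNF287, URI1 and SLC12A8 lost theirs, and with late as 8 to 24 h GDF11 and GUCY1A1 did. Limma called 1711 probe sets, 791 higher and 920 lower, for 623 genes higher and 663 lower. Without the 6, 8, 12 or 24 h pair the count was 768, 1108, 731 or 396.

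Of 7 metallothionein genes, 5 were higher late and 2 did not pass, with 6 higher adjusted over the list alone. MT1X was at 1.16 ± 0.22 and MT1E at 1.09 ± 0.16. The median was 0.95 (adjusted p = 0.000115, and adjusted p = 0.415 with an estimated correlation), and the start array lay 1.01 from the controls. Of 54 oxidative phosphorylation genes, 20 were lower and 34 did not pass, with 23 lower adjusted over the list alone, and COX6C was at -0.74 ± 0.10. Their adjusted p was 3.65e-09, and 0.415 with an estimated correlation. Of 17 cholesterol genes, 1 was higher, 6 lower and 10 did not pass, with 2 and 8 adjusted over the list alone, and FDPS was at -0.86 ± 0.18. The median was -0.36 (adjusted p = 0.00574, and adjusted p = 0.415 with an estimated correlation), and without the 6 h pair the adjusted p was 0.0701. These lists were also called after quantile normalization. Of the list members named in this window, 47 in all, 30 kept their call without the 6 h pair, 35 without the 8 h pair, 32 without the 12 h pair and 22 without the 24 h pair. Without the filter on low values 16 kept it, and FDPS, GARS1, MT1X, MT1E and MS4A1 were among those that lost it. With late as 8 to 24 h 25 kept it, and without the intensity trend 28 did.

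The ribosomal protein list, with 35 of 52 lower and 17 not passed and 44 lower adjusted over the list alone, had a late median of -0.45 (adjusted p = 3.99e-22, and adjusted p = 0.415 with an estimated correlation) that turned to 0.018 after quantile normalization. Of 16 aminoacyl-tRNA synthetases, 4 were lower and 12 did not pass, with 7 lower adjusted over the list alone, and GARS1 was at -0.64 ± 0.14. For the list the adjusted p was 0.00239, against 0.415 with an estimated correlation and 0.0522 after quantile normalization, and the median of -0.31 stood beside -0.37 for the start array. Of 24 amino acid response genes, 4 were lower and 20 did not pass, with 5 lower adjusted over the list alone, and the glutamine transporter SLC1A5 was at -0.77 ± 0.12. By camera the adjusted p was 0.0151, against 0.507 with an estimated correlation and 0.117 after quantile normalization, and the median of -0.24 stood beside -0.41 for the start array. The remaining late calls each had an adjusted p of 0.415 with an estimated correlation. Proteasome genes (3 higher, 5 lower, 24 not passed, with 4 and 15 adjusted over the list alone) had an adjusted p of 0.00574, and 0.641 after quantile normalization. Translation factors (6 lower, 24 not passed, with 1 higher and 8 lower adjusted over the list alone) had a median of -0.11 and an adjusted p of 0.00574, which became a median of 0.038 and 0.911 after quantile normalization and 0.0869 without the 24 h pair. DNA replication genes (8 lower, 35 not passed, with 1 and 8 adjusted over the list alone) had 0.0153, which became 0.0522 after quantile normalization and 0.0995 without the 6 h pair.

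G1/S genes (4 lower, 17 not passed, the same adjusted over the list alone) had a late adjusted p of 0.0253, which became 0.144 after quantile normalization and 0.0995 without the 6 h pair, and adjusted p = 0.415 with an estimated correlation. Genes of the spliceosome (6 lower, 43 not passed, with 1 and 9 adjusted over the list alone) had 0.0354, which became 0.685 after quantile normalization and 0.0754 and 0.0917 without the 6 and 24 h pairs. Genes of intestinal differentiation (2 higher, 13 not passed, with 5 higher adjusted over the list alone) had 0.0466, which became 0.271 after quantile normalization and 0.097 and 0.0721 without the 6 and 24 h pairs. GPA33 was at 1.33 ± 0.25. Of 9 leukocyte markers 1, the B cell antigen MS4A1, was higher at 0.92 ± 0.20 and 8 did not pass, with 3 higher adjusted over the list alone. That list had an adjusted p of 0.0466, which became 0.237 after quantile normalization and 0.0516, 0.0686 and 0.114 without the 2, 6 and 24 h pairs, and its median was 0.48 against 0.52 in the start array. MS4A1 had an intensity of 125 to 183 in the late induced arrays and 132 in the start array.

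Alpha-globin was singled out after its values were seen, since probe sets shared by several genes fall outside the naming rule. The 5 tested alpha-globin probe sets were higher late, at 1.81 to 2.72 on the log2 scale (limma adjusted p = 0.0138 to 0.0353). Their intensities are shown in the plot of globin probe sets. Without the 12 h pair the adjusted p was 0.0684 to 0.127 and without the 24 h pair 0.057 to 0.157, so all 5 lost their call, and after quantile normalization 4 of 5 were called. In the slope of the difference on log2(hours) 4 of 5 were called, and for late minus early they stood at 2.30 to 3.49 with none called (adjusted p = 0.113 to 0.236).

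The difference between the late and the early effect was tested directly. NFKBIA, the inhibitor of NF-kB, moved from lower to higher in the induced arrays relative to the controls, with a difference of 2.49 ± 0.46 (adjusted p = 0.0389). It is also among the falls named for the trend in controls, where it did not pass. FGFR3 had 2.29 ± 0.33, INSIG1, a brake on sterol synthesis, 1.84 ± 0.24, the small heat shock protein HSPB1 1.66 ± 0.22, IDI1 1.55 ± 0.23 and MSRB1 1.47 ± 0.24. In the other direction, CEBPG had -1.58 ± 0.20 (adjusted p = 0.0101), the histone methyltransferase EZH2 -1.55 ± 0.23, the aspartate aminotransferase GOT1 -1.54 ± 0.24, the neurotrophin BDNF -1.52 ± 0.27, ADAM9 -1.48 ± 0.23 and IBTK -1.47 ± 0.24. NFKBIA and FGFR3 were at the floor in 1 induced array each. Limma called 45 probe sets, 22 with a higher and 23 with a lower late effect, for 18 and 22 genes. Of the 45, 10 were also called within the induced arrays alone, all 10 in the same direction. Within the control arrays alone 11 were called, 0 of them in the same direction. The difference is the change in the induced arm minus that in the control arm, from the same arrays. These directions therefore largely follow from the subtraction and the selection, and cannot tell in which arm the difference arose. The count of 45 became 5 without the 1 h pair, 8 without the 2 h pair, 79 without the 4 h pair and 25 without the 8 h pair. Of the 12 genes named here, 1 kept its call without the 1 h pair (INSIG1) and 1 without the 2 h pair (CEBPG), and 10, 11, 9, 9 and 10 did without the 4, 6, 8, 12 and 24 h pairs. None of the 12 kept its call without the filter on low values, without the intensity trend or with early as 1 and 2 h, and 7 kept it without the time block. The 8 probe sets called with early as 1 and 2 h shared 0 with the 45. KLF4 on its more responsive probe set was at 2.27 ± 0.59 (adjusted p = 0.112), and passed with the floor at the 40th percentile (adjusted p = 0.0256) and with array weights (adjusted p = 0.0395).

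The list test of this difference was added after the data were seen. Camera called 11 lists, 9 higher and 2 lower late, and 0 with an estimated correlation. Of 17 cholesterol genes, 2 (IDI1 and INSIG1) had a higher late effect and 15 did not pass, with 9 adjusted over the list alone. The median was 0.58 (adjusted p = 2.21e-08, and adjusted p = 0.193 with an estimated correlation). Of 24 amino acid response genes, 1 (CEBPG) had a lower late effect and 23 did not pass, with 11 adjusted over the list alone. The median was -0.68 (adjusted p = 4.72e-08, and adjusted p = 0.31 with an estimated correlation). Leaving out each pair in turn moved it between -0.914 and -0.358, the latter end being the smaller effect. Of 32 proteasome genes, PSMD3 at 1.04 ± 0.19 and PSMD4 at 1.00 ± 0.19 had a higher late effect and 30 did not pass, with 11 adjusted over the list alone (list adjusted p = 2.27e-08, and adjusted p = 0.193 with an estimated correlation). PSMD3 lost its call without the 1, 2, 4, 6, 8 or 24 h pair, and PSMD4 without the 1, 2, 4, 8, 12 or 24 h pair. Both lost it without the filter on low values, without the intensity trend, without the time block and with early as 1 and 2 h. Of 19 heat shock proteins, HSPB1 and SERPINH1, at 1.44 ± 0.20, had a higher late effect and 17 did not pass, with 6 higher and 1 lower adjusted over the list alone. SERPINH1 lost its call without the 1 h pair, the filter, the intensity trend or the time block, and with early as 1 and 2 h. The list's adjusted p was 0.0188, which became 0.475 with an estimated correlation and 0.136, 0.0828 and 0.0873 without the 1, 6 and 8 h pairs. In 5 lists 0 members passed by limma over all genes. These were the synthetases (16 genes, 2 lower adjusted over the list alone, median -0.50, adjusted p = 1.87e-05, and adjusted p = 0.193 with an estimated correlation), the metallothioneins (7 genes, 3 higher, median 0.81, adjusted p = 2.19e-05, and 0.31), fatty acid synthesis (8 genes, 2 higher, median 0.31, adjusted p = 0.00573, and 0.193, with the start array -0.18 from the controls), G2/M and mitosis (46 genes, 0 adjusted over the list alone, median 0.21, adjusted p = 0.00573, and 0.655) and hypoxia and glycolysis (32 genes, 3 higher and 1 lower, median 0.23, adjusted p = 0.0208, and 0.248). The G2/M adjusted p was 0.212 without the 4 h pair and 0.534 without the 12 h pair, and the hypoxia value 0.163 without the 4 h pair and 0.0512 without the 24 h pair. All of these lists were also called after quantile normalization.

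A pair of further calls did not hold under that scaling. The ribosomal protein list, of which 1 member passed as lower late and 51 did not pass, the same adjusted over the list alone, had a median of 0.16 (adjusted p = 0.024, and adjusted p = 0.655 with an estimated correlation) that turned to -0.076 with a call in the opposite direction after quantile normalization (adjusted p = 0.0227). Its adjusted p was 0.792, 0.284 and 0.218 without the 4, 6 and 8 h pairs. Of 12 housekeeping genes, the transferrin receptor TFRC had a higher late effect, at 1.12 ± 0.18, and 11 did not pass, with 3 adjusted over the list alone. TFRC lost its call without the 1, 2, 8, 12 or 24 h pair. It also lost it without the filter on low values, the intensity trend or the time block, and with early as 1 and 2 h. The list's adjusted p of 0.0103 became 0.193 with an estimated correlation, 0.068 after quantile normalization and 0.0779 without the 4 h pair.

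**Figure D3:**
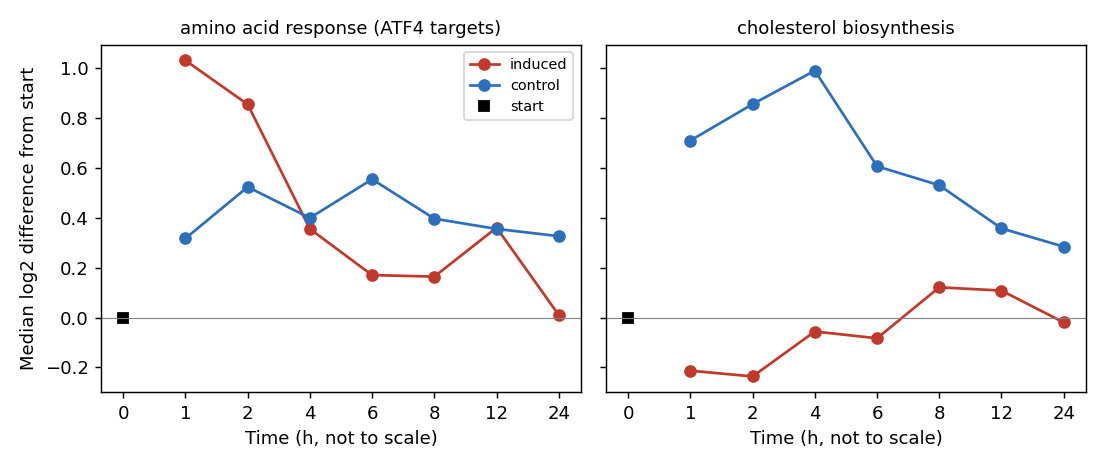
Median log2 difference from the start array of the amino acid response list (24 genes) and the cholesterol biosynthesis list (17 genes) against time in hours, for the induced and control arms, 1 array per point. The amino acid response lies at 1.03 in the induced arm and 0.32 in the control arm at 1 h, and the cholesterol list at -0.21 and 0.71.

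In the control cells, ID1, an inhibitor of basic helix-loop-helix factors and a TGF-beta target, rose with time, by 0.37 ± 0.05 per unit of log2(hours + 1) (limma adjusted p = 0.0358). Its intensity was 496 in the start array, 626 in the control array at 1 h and 1413 at 24 h. The related ID2 and ID3 had slopes of 0.41 ± 0.07 (adjusted p = 0.27) and 0.34 ± 0.06 (adjusted p = 0.251). ID1 was the 1 probe set called, and 831 had an unadjusted p under 0.05. Without any 1 of the 7 control arrays limma called 0, with 639 to 992 probe sets at an unadjusted p under 0.05, and without the start array it called 4. ID1 was not among these 4, so it lost its call without any 1 of the 8 arrays. Genes named by the rule that did not pass were ANKRD1 (0.49), TSKU (0.47), FKBP10 (0.46), CBX7 (0.44), ZNF358 (0.44) and MPPE1 (0.43), and IL15RA (-0.55), TBCD (-0.47), MT1HL1 (-0.45), GP9 (-0.45), IL19 (-0.44) and NFKBIA (-0.43). IL15RA, TBCD and GP9 were at the floor in 2 control arrays each, and IL19, CBX7 and ZNF358 in 1 each.

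Camera called 5 lists for the trend in controls, and 0 with an estimated correlation. None of the 5 kept its call without the start array, which the first principal component placed with the induced arrays. Their slopes therefore cannot be told apart from a step between the start array and the controls. Ribosomal proteins (0 of 52 passed, 0 adjusted over the list alone) had a median slope of 0.072 (adjusted p = 7.32e-08, and adjusted p = 0.759 with an estimated correlation), which was 0.0010 after quantile normalization (adjusted p = 0.717) and turned to -0.020 without the start array (adjusted p = 0.335). Metallothioneins (0 of 7 passed, 4 lower adjusted over the list alone) had -0.18 (adjusted p = 7.7e-05, and adjusted p = 0.299 with an estimated correlation), and an adjusted p of 0.215 without the start array. Ribosome biogenesis (0 of 31 passed, 0 adjusted over the list alone) had -0.060 (adjusted p = 0.00352, and 0.299), and 0.0731 without the start array, which lay 0.16 from the controls. Leukocyte markers (0 of 9 passed, 0 adjusted over the list alone) had -0.12 (adjusted p = 0.0312, and 0.299), and 0.37 without the start array. TGF-beta targets (1 of 18 passed, ID1, with 3 higher adjusted over the list alone) had 0.037 (adjusted p = 0.0312, and 0.299), and the start array lay -0.42 from the controls. Without the start array their median was -0.011, although camera's direction stayed upward, with an adjusted p of 0.651, and without the control array at 4 h the adjusted p was 0.0536.

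At single times, with no test possible, the number of probe sets that differed at least 2-fold between the arms was 1471 at 1 h, 1365 at 2 h, 2505 at 4 h, 910 at 6 h, 1020 at 8 h, 1149 at 12 h and 1361 at 24 h. Between control arrays of neighbouring times it was 394 to 1332, and between the start array and the control at 1 h it was 1248. Against the start array, the induced arrays differed in 331 to 822 probe sets and the control arrays in 853 to 2103. The differences between the arms at any 2 times correlated across probe sets at 0.293 to 0.575.

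**Figure D4:**
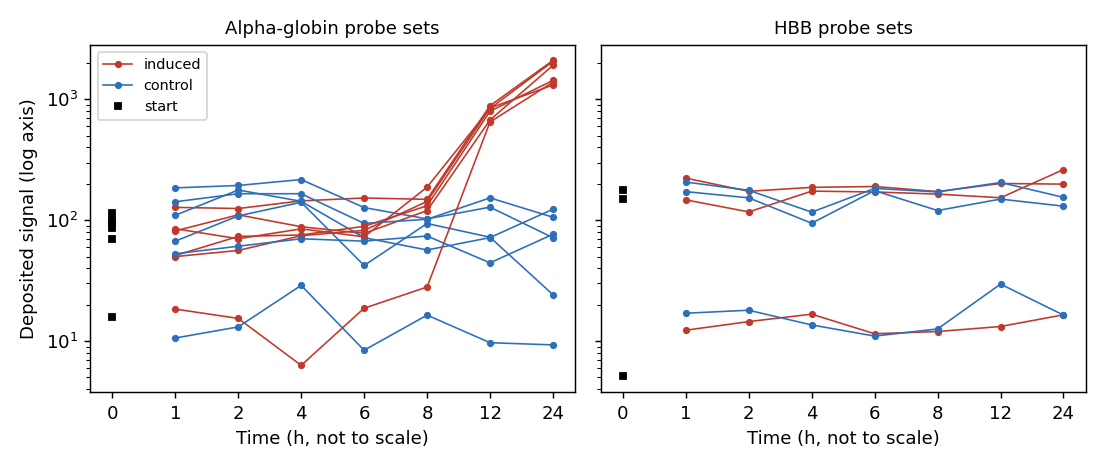
Intensity on a log axis of the alpha-globin probe sets, each shared by both alpha-globin genes, and of the HBB probe sets in each array by time in hours and arm. The alpha-globin sets lie between 649.7 and 2096.9 in the induced arrays at 12 and 24 h and at most at 216.9 in the others, and the HBB sets lie between 13.2 and 262.3 in those induced arrays.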

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

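The tests of a technical array set, of KLF4 as the whole cause, of signal compression between the arms, of the control arm, of a transient rise or fall and of adult blood RNA were chosen after the results they measure had been seen, as were the list test of late minus early and the comparisons within 1 arm. The erythroid test was written earlier, although the HBB probe sets among its 24 had been seen.

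The first pattern is the difference between the arms from 1 h on, before the KLF4 signal differed on its more responsive probe set. If a technical set of arrays accounts for it, the start array, which had no inducer, should differ from the controls as the induced arrays do. Over 1302 probe sets called from the 1, 4, 8 and 24 h pairs, the start array minus the controls at 2, 6 and 12 h held a median share of 0.759 of the effect (quartiles 0.467 to 0.97), which is consistent with such a set, while 133 of them had a share below 0.2. KLF4 as the whole cause needs effects that are absent before it rose. Over 1730 probe sets called from the 4 late pairs fitted alone, the median share already present at 1 and 2 h was 0.819 (quartiles 0.407 to 1.2), with 277 below 0.2. This argues against KLF4 as the whole cause only if its probe sets follow the induced KLF4, which was not tested, since they need not see a transgene. Signal compression of the kind that quantile normalization removes, as the whole cause, is argued against by the 71.4% of average calls kept in direction after it. Compression that this scaling does not remove was not tested. The highest intensity was 6717.5 to 8266.5 in the induced arrays, 7537.5 in the start array and 10063.9 to 20349 in the control arrays. A response of the control cells to vehicle or handling was not tested and stays open, as does a part of the effect due to ponasterone A or KLF4.

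The second pattern is the early change of the amino acid response and cholesterol lists. The pair at 4 h alone does not account for it, since without that pair the late minus early median was -0.914 for the amino acid response (camera adjusted p = 6.82e-13) and 0.576 for cholesterol (adjusted p = 3.03e-07). With all pairs, neither list was called at an estimated correlation. Leaving out each pair in turn gave medians of -0.914 to -0.358 for the amino acid response, with the highest camera adjusted p, 0.00143, without the 1 h pair. For cholesterol it gave 0.494 to 0.744. For the amino acid response, a change in the control arm is argued against by a share of -0.0627 of the difference within that arm. A transient rise in the induced arrays after the start would give what was seen there, a median of 0.889 at 1 and 2 h, higher in 24 of 24 genes, and 0.107 late. The control arm lay 0.42 above the single start array at 1 and 2 h and 0.417 late. That near-constant distance also holds the grouping of the arrays, so it cannot tell whether a part of the rise is shared by the control arm. For cholesterol the control arm held a share of 0.513. The induced arrays lay -0.234 from the single start array at 1 and 2 h, with an SE of 0.0854 over the 17 genes, not over arrays. That SE was weighed against the bound only after the value was seen. Late minus early, the cholesterol median was 0.267 within the induced arm and -0.296 within the control arm, so each arm holds part of the difference. The cause of the change in either arm was not settled. A response to the inducer or to handling at the start stays open, while KLF4 signal differed between the arms by only 0.08 at 1 h and -0.02 at 2 h on its more responsive probe set.

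The third pattern is the alpha-globin signal, chosen after its values were seen, of which 5 probe sets were tested and higher late and 1, outside the tests, reached 1385.2 in the induced array at 24 h. Its 6 probe sets, shared by both genes, lay at 649.7 to 886.1 in the induced array at 12 h and 1313.8 to 2096.9 at 24 h, and at most at 216.9 in all others. RNA from adult blood would raise HBB with it, but the median log2 difference between the arms at 12 and 24 h over the 3 HBB probe sets was 0.168. Erythroid cells would bring their other abundant transcripts, but over 24 erythroid probe sets the median of the same log2 difference was 0 (range -1.16 to 0.892), with 0 reaching 1. No biological explanation was tested, and KLF4 induction stays open.

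Other splits of the same samples were fitted in the same way. For the average effect 1 of 64 splits, the real one, gave as many calls (4292, highest other 5). The arrays already group by arm, so a flipped pair moves that grouping into the residual and lowers the count. The splits therefore cannot tell an effect of induction from the grouping. As many lists came from 4 of 64 splits (12, highest other 12), so chance cannot be excluded for them. For the early effect (3090 calls, highest other 0, and 15 lists, highest other 8, 1 of 4 splits each) and the late effect (1711 calls, highest other 0, and 13 lists, highest other 9, 1 of 8 splits each) the splits are too few for a share under 0.05. For late minus early 1 of 35 splits, the real one, gave as many calls (45, highest other 2). The same held within the induced arrays (16, highest other 7, 1 of 35) and within the control arrays (24, highest other 1, 1 of 35). The real split divides the course in order of time, so a drift over the single arrays is not excluded. For the lists of late minus early 2 of 35 splits gave as many (11, highest other 11), so chance cannot be excluded. For the trend in controls 3 of 100 splits gave as many calls (1, highest other 1), a share under 0.05 of a count that other splits also gave, so it can hardly tell the splits apart, and 45 of 100 gave as many lists (5, highest other 12), so chance cannot be excluded.

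Of 80 groups of values tested for a sample far from the others, 7 had one, and chance gives about 1 in 20. The gap as a share of the range was 0.588 for 1 RXRA probe set (4 h) and 0.616 for another (24 h), 0.621 for SLC13A3 (8 h), 0.625 for CPA3 (24 h), 0.68 for PLEKHG3 (8 h), 0.759 for IL19 (24 h) and 0.648 for the 2-fold count (4 h, 2505). The test of the difference between windows called 45 probe sets, among them NFKBIA (2.49), FGFR3 (2.29), INSIG1 (1.84), HSPB1 (1.66), IDI1 (1.55), MSRB1 (1.47), CEBPG (-1.58), EZH2 (-1.55), GOT1 (-1.54), BDNF (-1.52), ADAM9 (-1.48) and IBTK (-1.47). Outside the tested probe sets, the 18S control probe sets were at least 10.4-fold higher in the control than in the induced arrays, with induced values raised to the floor of 22.3. The ratio of the deposited values, 27.8, rests on induced values mostly below that floor and is not a measured fold.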

How the results depend on the processing

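The alternatives for alpha-globin, the comparisons within 1 arm, the list test of late minus early, and the slope over the induced and start arrays, were chosen after seeing the data. Of 5318 alternative values of named genes, 4853 kept direction and side of the threshold, 412 lost and 38 gained a call, 12 moved and 3 reversed. The reversals were all under quantile normalization: EEF1A1 (0.087 on average, 0.096 late) and EEF2 (0.0066 on average). Under that scaling the median effect over all probe sets shifted by at most 0.1 on the log2 scale, early from 0.0752 to 0.025. Single lists moved further, and the early ribosomal protein median turned to 0.0955 with a call in the opposite direction. The cause was not tested for any change below, except where fewer arrays were used. Without a filter limma called 1885 early, 528 late, 1 for late minus early (2088 at an unadjusted p under 0.05) and 0 for the control trend (1369 unadjusted). Without the intensity trend it called 1115 late, 0 for late minus early (1528 unadjusted) and 0 for the control trend (800 unadjusted). Late minus early gave 88 with the floor at the 40th percentile, 196 with array weights, 22 without the time block, 16 in the induced arrays, 24 in the control arrays and 0 for the slope over induced and start arrays (899 unadjusted). With early as 1 and 2 h the counts were 1047 early, 3206 late and 8 for the difference, and with late as 8 to 24 h 695 late. The slope on hours gave 0 for the control trend (675 unadjusted). With an estimated correlation camera called 0 lists in each of the 5 comparisons. Fry called 20 on average, 4 for late minus early and 0 for the control trend, and under quantile normalization camera called 4 on average, 3 of the 12 and metallothioneins (adjusted p = 0.0474, against 0.0543), and 3 late, all among the 13. The KLF4 difference was 1.74 after quantile normalization (exact p = 0.0625). The median 2-fold count over the times was 3768 at a ratio of 1.5 and 396 at a ratio of 3. Leaving out 1 pair or array gave 3253 to 4120 calls on average, 1645 to 3061 early (1645 without 4 h), 396 to 2143 late (396 without 24 h), 5 to 79 for late minus early (5 without 1 h, 79 without 4 h) and 0 to 4 for the control trend (4 without the start array, 639 to 992 unadjusted). It gave 7 to 15 lists late and a KLF4 difference of 1.51 to 2.23. Deviations from the arm mean correlated weakly between the arms at the same time, at -0.0123 to 0.196. Signals near the floor of 22.3 limit what low transcripts can show.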

Other observations

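The comparisons in this part were all added after the data were seen, and their lists were not tested under quantile normalization. Within the induced arrays alone, immediate early genes, the first transcripts to answer a stimulus, were lower late than early. Of 29 measured, 1 fell and 28 did not pass, with 1 higher and 9 lower adjusted over the list alone, and the median was -0.32 (camera adjusted p = 4.49e-08, and adjusted p = 0.379 with an estimated correlation), and the start array lay -0.18 from the mean of the controls. Of 24 genes of the unfolded protein response, 1 fell and 23 did not pass, with 5 lower adjusted over the list alone (median -0.16, adjusted p = 0.000793, and adjusted p = 0.449 with an estimated correlation, with the start array -0.18 from the controls). Of 16 aminoacyl-tRNA synthetases, 0 passed by limma over all genes and 11 were lower adjusted over the list alone (median -0.58, adjusted p = 3.66e-10, and adjusted p = 0.379 with an estimated correlation). In all, camera called 12 of 37 lists late minus early within the induced arrays, 7 higher and 5 lower, and 0 with an estimated correlation or by fry. Of 24 amino acid response genes, 1 fell and 23 did not pass, with 15 lower adjusted over the list alone (median -0.70, adjusted p = 5.17e-13, and adjusted p = 0.379 with an estimated correlation). Of 19 heat shock proteins, 2 rose and 17 did not pass, with 5 higher and 1 lower adjusted over the list alone (median 0.45, adjusted p = 0.000264, and 0.571). In the other 7 called lists 0 members passed over all genes. These were the metallothioneins (7 genes, 5 higher adjusted over the list alone, median 0.82, adjusted p = 1.42e-05, and 0.449 with an estimated correlation), the proteasome (32 genes, 7 higher, median 0.29, adjusted p = 2.51e-07, and 0.449), cholesterol biosynthesis (17 genes, 4 higher, median 0.27, adjusted p = 0.000793, and 0.449), core histones (8 genes, 1 higher, median 0.21, adjusted p = 0.0472, and 0.571), G2/M and mitosis (46 genes, 0 adjusted over the list alone, median 0.19, adjusted p = 0.00192, and 0.702), DNA replication (43 genes, 0, median 0.18, adjusted p = 0.00735, and 0.571) and translation factors (30 genes, 0, median -0.18, adjusted p = 0.00735, and 0.61). Limma called 16 probe sets in this comparison, with 1416 at an unadjusted p under 0.05.

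Within the control arrays alone, the same 29 immediate early genes had a late minus early median of -0.25, with 0 passed over all genes and 2 higher and 9 lower adjusted over the list alone (adjusted p = 0.00241, and adjusted p = 0.568 with an estimated correlation). The 24 genes of the unfolded protein response were called lower here too, with 0 passed over all genes and 2 lower adjusted over the list alone (median -0.078, adjusted p = 0.0402, and adjusted p = 0.568 with an estimated correlation). Of 17 cholesterol genes, 1 fell and 16 did not pass, with 2 lower adjusted over the list alone (median -0.30, adjusted p = 0.000116, and adjusted p = 0.568 with an estimated correlation). Of 12 Wnt targets, 0 passed over all genes and 4 were higher adjusted over the list alone (median 0.22, adjusted p = 0.0402, and adjusted p = 0.568 with an estimated correlation, with the start array 0.062 from the controls). Of 52 ribosomal proteins, 1 rose and 51 did not pass, the same adjusted over the list alone, although the list was called lower (median -0.14, adjusted p = 0.000163, and adjusted p = 0.568 with an estimated correlation). These are the 5 of 37 lists that camera called, 1 higher and 4 lower, with 0 called with an estimated correlation and 1, the Wnt targets, by fry. Limma called 24 probe sets, with 1660 at an unadjusted p under 0.05.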
